A study of Homo sapiens with 4 samples.

How the data were processed

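The data are amplicon counts of 4 RNA libraries from 1231A3 human induced pluripotent stem cell-derived neural crest cells, 1 library per group. Per the labels' protocols, 10 ng of total RNA per library was reverse transcribed and amplified for 13 cycles with a multiplex PCR panel for human genes (Ion AmpliSeq Transcriptome), which reads 1 amplicon per gene, on the Ion Chef. The deposited values are raw read counts per amplicon target, per the file headers, and they were whole numbers with a different total in each library. The submitters' processing notes name the hg19 build and DESeq2. The aligner, the counting program and their versions are not given in the sources used here, nor is the treatment of reads shared between near-identical genes, so values of genes with close copies, such as PPIA, RPLP0 and HSPA1A, are uncertain. Molecular identifiers were not part of the protocol, and PCR copies of a molecule count as separate reads.

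The table had 20812 entries. Of these, 28 carried dates in place of gene names, a known effect of spreadsheet programs, and were left out of library sizes and calls, and 10 were spike-in controls with 0 reads in every library. Sex-chromosome-specific genes, 68 entries, were left out of all results, leaving 20706 genes. The libraries held 10935169, 11065698, 5661291 and 9294533 reads (aggregates before and after FEDB, 2D cells before and after FEDB). A count of 0 is treated as up to 3 reads, which corresponds to 0.27, 0.254, 0.496 and 0.378 scaled CPM in that order.

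Counts were scaled with edgeR 4.0.16 by the trimmed mean of M values (TMM, factors 1.019, 1.07, 1.07 and 0.857) in R 4.3.3 and expressed as CPM, the scaled share of each library's reads on the usual scale. Ratios were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Counts under 3 were set to 3 when a ratio was held to a limit and for ratios against 0 reads, which are given as "at least". A fold printed against 1 or 2 reads uses the reads themselves, so it can exceed a bound against 0 reads and has a wide interval. No ratio is given where both libraries had 3 reads or fewer. Intervals are exact 95% Clopper-Pearson intervals conditional on the pair's counts. A gene was counted as higher or lower when its ratio was at least 2, its interval excluded 1 and the higher library had at least 10 CPM. The difference of the FEDB responses is a ratio of ratios with a normal 95% interval on the log scale, 0.5 added to each count, and the same limits. DESeq2 1.42.0 and edgeR served for scaling factors only. No p-value or standard error was computed, because each group has 1 library.

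The 4 comparisons were after against before FEDB in aggregates and in 2D cells, and 2D cells against aggregates before and after FEDB. The design, the alternatives and 40 gene lists with 468 entries, of which 463 matched the table, were fixed before the data were examined. A list's median log2 ratio (1 CPM added) was taken over its members with at least 10 CPM in any library and, with 3 or more such members, set among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. A gene shared by several lists counts in each of them. CYR61, CTGF and LECT1 appear under these older symbols, as in the table.

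The genes named are, per comparison, the 10 with the highest and the 10 with the lowest ratios by the interval bound nearest 1 among protein-coding symbols, up to 4 members per list with the largest ratio in the list's main direction, the 10 largest differences of the responses each way, and 13 genes always named: NGFR, EDNRA, HAND1, HAND2, DLX5, DLX6, MSX1, MSX2, SOX10, TFAP2A, SOX9, TWIST1 and PRRX1. Values of a named gene in other comparisons are given as levels. Some genes picked by these rules are not reported here.

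Alternatives were DESeq2 size factors, total counts, upper-quartile scaling, scaling to 19 reference genes, minimums of 1 and 30 CPM or none, ratios of 1.5 and 4, a 99.99% interval, 0.25 or 5 CPM added, library sizes without the 20 highest amplicons and counts thinned to the smallest library. After the data were seen a correction for GC content was added, which takes out each library's median deviation in 20 bins of the GC of the longest GENCODE 29 transcript (98.4% of the measured genes had one), as was a comparison of 2D cells after FEDB with aggregates before FEDB. The amplicon sequences were not used here, so transcript GC stands in for amplicon GC. The reference annotation is of another build than hg19, so no coordinates are given.

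The procedure was tested on simulated counts of 20706 genes with 200 changed genes. With Poisson noise alone no unchanged gene was counted in any comparison and 100% of genes changed 3-fold were recovered. With a coefficient of variation of 0.2 between libraries, 183 (FEDB in aggregates) to 220 (2D against aggregates after FEDB) unchanged genes were counted, and with 0.4 between 2257 and 2360, while 98% to 100% of genes changed 8-fold were recovered. Of genes changed 3-fold, 84% to 95% were recovered with 0.2 and 68% to 77% with 0.4. The difference of responses was simulated with Poisson noise alone, and recovered 100% of 4-fold changes with 5 unchanged genes counted. Its behaviour with variation between libraries was not simulated. Of 200 random lists, 14 fell outside the 2.5 to 97.5 percentiles, and 50 of 50 lists changed 3-fold were found. The GC correction reduced a planted gap of 2.63 between the outer deciles to 0.10.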

Results

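Transcript levels were measured by amplicon-based RNA sequencing in neural crest cells made from 1231A3, a human induced pluripotent stem cell line. The neural crest is the migratory embryonic population that gives rise to the facial skeleton, peripheral neurons, glia and pigment cells. The comparison of interest was the effect of FEDB, a mixture of FGF8b (100 ng/ml), endothelin-1 (50 nM) and BMP4 (2.5 ng/ml), on neural crest cells induced in flat (2D) culture, set beside its effect on neural crest cells held as aggregates on a shaker. There were 4 libraries, 1 per group: aggregates before FEDB (culture day 5), aggregates after 4 days of FEDB (day 9), 2D-induced cells sorted for high CD271 before FEDB, and such cells after 4 days of FEDB on fibronectin. The libraries held 10935169, 11065698, 5661291 and 9294533 reads in that order, and between 15083 and 15912 amplicon targets had at least 1 read. With no replicates, no difference below has a replicate check and no test was made. The range in parentheses after a fold is its 95% counting interval, which covers counting error only, and "higher" or "lower" compares libraries. The interval takes each read as an independent count, although PCR copies of a molecule were not told apart, so it may be too narrow even for counting error. No library of cells kept for 4 days without FEDB was analysed here, so each difference after FEDB includes the effect of 4 days of culture.

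The sort marker was compared first. NGFR, which encodes CD271, stood at 226 CPM (read counts scaled to library size) in the sorted 2D cells and at 95.6 CPM in the aggregates before FEDB, a 2.36-fold difference (2.18 to 2.56). With a correction for transcript GC content, which is 62.8% for NGFR, the ratio was 1.17. The neural crest regulator SOX10 was at 645 and 487 CPM in those libraries.

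Read counts in the 2D library before FEDB went with transcript GC content. Among genes within 1.5-fold of each other in the other 3 libraries, Spearman's rho of a library's deviation with GC was 0.499 for the 2D library before FEDB and -0.379 for the aggregates before FEDB, against -0.04 and 0.0331 for the aggregates and 2D cells after FEDB. In 2D cells over aggregates before FEDB the median log2 ratio went from -0.96 in the decile of genes with the lowest transcript GC content to 0.83 in the decile with the highest, and Spearman's rho with GC was 0.52 across 10230 genes, which are not independent replicates. It was -0.32 for FEDB in 2D cells and 0.19 for FEDB in aggregates. For 2D cells over aggregates after FEDB, which leaves out both libraries taken before FEDB, it was -0.0089. Of 2164 genes within 1.5-fold of each other in the other 3 libraries, 131 were at least 4-fold lower in the 2D library before FEDB, against 2 to 13 genes for each of the others. RMND5A, for instance, stood at 0.165 CPM there and between 123 and 178 CPM elsewhere. GC-corrected medians are given beside several of the lists that rest on this library.

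**Figure D1:**
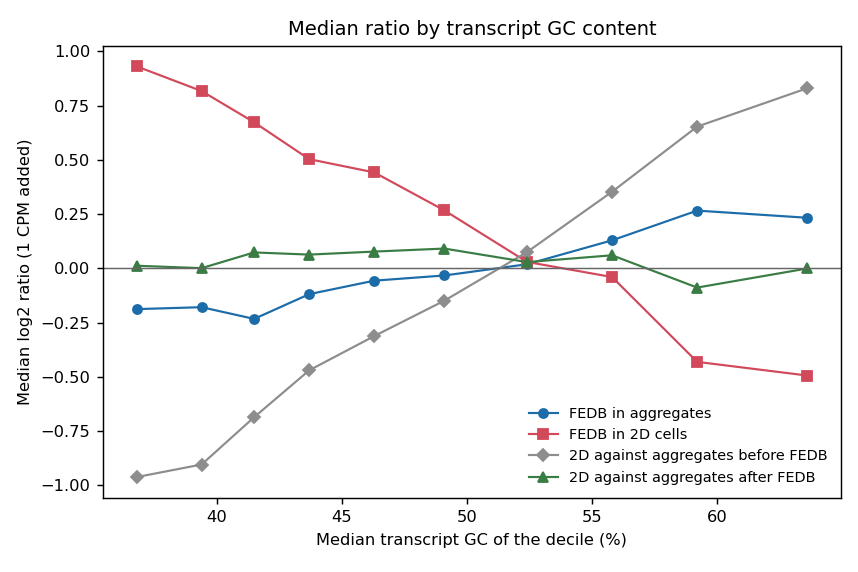
Median log2 ratio (y axis, 1 CPM added) of genes in deciles of transcript GC content (x axis, percent), 1 line per comparison and 1023 genes per point. The line for 2D cells over aggregates before FEDB climbs from -0.96 to 0.83, while the line for the same comparison after FEDB stays within 0.10 of 0.

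The first comparison was aggregates after against before FEDB. After FEDB the aggregates held high levels of the transcription factor genes that pattern the mandibular part of the first pharyngeal arch. HAND2, an endothelin-dependent regulator of the lower jaw, went from 0 reads to 566 CPM, at least 2097-fold higher, and DLX6 from 0 reads to 142 CPM, at least 526-fold higher. DLX5 was 41.0-fold higher (31.4 to 54.6) and GSC 334-fold higher (92.1 to 2764), the latter from 2 reads. MSX1 was 6.6-fold (5.39 to 8.13) and MSX2 6.46-fold (5.83 to 7.16) higher, whereas HAND1 stayed at 1 read in each library. Of the 12 measured mandibular and distal arch regulators, 10 were higher and 1 lower, with a median log2 ratio of 3.09, above all 10000 random lists of matched expression. Among 8 maxillary and proximal regulators, 6 were higher and none lower (median 1.91, also above every random list), including DLX1 at 30.4-fold (23.5 to 40.0), MEIS2 at 5.87-fold and DLX2 at 4.82-fold. The oral-side regulator BARX1 was at least 526-fold higher.

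Genes of ectomesenchyme, the crest lineage that forms facial skeleton and connective tissue, were higher as a group. Of 12 measured, 11 were higher and none lower, with a median log2 ratio of 4.31, above every random list. TWIST1 went from 4.95 to 506 CPM, 102-fold higher (78.5 to 136), FLI1 was 190-fold (80.9 to 585) and FOXC1 76.6-fold (43.7 to 149) higher, and PRRX1 was at least 90.0-fold higher, from 0 reads. Fibrillar and mesenchymal matrix genes followed, with 11 of 16 higher and none lower (median 2.66), among them LUM at 134-fold (93.9 to 199), COL1A1 at 49.2-fold (40.4 to 60.5), COL3A1 at 22.5-fold (12 to 47.5) and COL6A2 at 12.3-fold (10.2 to 14.9). Smooth muscle and myofibroblast genes were higher in 5 of 9, with ACTA2 at 6.98-fold (5.69 to 8.66) and TPM1 at 4.68-fold (4.24 to 5.19). TGF-beta and YAP targets were higher in 3 of 12, led by TGFBI at 19.4-fold (14.2 to 27.1). Cartilage genes went both ways, 3 higher and 4 lower of 11, with LECT1 25.2-fold (12 to 63.7) and COL9A3 7.19-fold (4.53 to 12) lower, and 2 of 6 bone genes were higher.

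Neural crest and glial genes were lower after FEDB in the aggregates. FOXD3 was 509-fold lower (174 to 2471), at 3 reads after FEDB, SOX10 18.7-fold lower (16.7 to 21.1) and PAX7 at least 81.1-fold lower, with 0 reads after. NGFR was 8.89-fold lower (7.39 to 10.8), while SOX9 was 2.88-fold higher (2.55 to 3.27) and TFAP2A stood at 374 CPM before and 329 CPM after. Of 15 neural crest specifiers, 9 were lower and 3 higher (median -1.89, below every random list). Of 9 Schwann cell and glial genes, 8 were lower and none higher (median -4.12, below every random list), including S100B at 120-fold (62.8 to 262), GFRA3 at 42.5-fold (14.2 to 209) and ERBB3 at 20.6-fold (17.8 to 24.1). Neuronal genes were lower in 2 and higher in 1 of 10, with NEUROG1 31.0-fold lower (13.0 to 97.0) and TUBB3 5.91-fold lower (5.21 to 6.73). Their median log2 ratio was -1.53, also below every random list. Several members, such as NEUROD1 (6.66 and 0.423 CPM) and POU4F1 (8.37 and 1.27 CPM), stayed under 10 CPM in both aggregate libraries and could not be called. The frontonasal regulators, 4 measured, were split, 2 higher and 2 lower, the lower ones being PAX7 and PAX3, both of which also sit among the crest specifiers.

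Targets of 2 of the added factors were higher in the aggregates. Feedback targets of FGF and ERK signalling were higher in 9 of 11 and lower in 1 (median 2.04, above every random list). DUSP6 was 25.2-fold (20.3 to 31.8), ETV4 18.7-fold (9.26 to 44.1) and SPRY2 12.2-fold (10.4 to 14.3) higher, and the lower one, EGR1, was 17.9-fold lower (13.1 to 25.2). BMP targets were higher in 6 of 10 and lower in none (median 2.10, above every random list), with ID1 at 22.3-fold (19.3 to 25.8) and SMAD7 at 7.96-fold (5.93 to 10.9). MSX1 and MSX2 count in this list as well as among the arch regulators. The endothelin receptors EDNRA and EDNRB were 4.11-fold (3.91 to 4.33) and 5.46-fold (3.82 to 7.99) lower, the only called members of 7 measured pathway genes. WNT targets were lower in 4 of 7 and higher in none (median -1.80, below every random list), with SP5 at least 164-fold lower, NKD1 18.4-fold (15.7 to 21.7) and AXIN2 3.94-fold (3.39 to 4.60) lower. Pluripotency genes were lower in 3 of 6, with SOX2 29.9-fold (20.4 to 45.6) and LIN28A 3.47-fold (3.39 to 3.56) lower.

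Among the largest ratios outside those groups, the parathyroid hormone receptor gene PTH1R was 623-fold (172 to 5149, from 2 reads), the peptidase inhibitor gene PI15 323-fold (164 to 748), the ephrin receptor gene EPHA3 275-fold (117 to 847), A2M 222-fold (127 to 431) and MAB21L2 190-fold (123 to 312) higher. The chemokine receptor gene CXCR4 was 504-fold lower (216 to 1553), ECEL1 160-fold lower (93.4 to 301) and the cadherin gene CDH6 63.1-fold lower (56.2 to 71.1). In all, 1283 genes were counted as higher and 958 as lower out of 9436, 263 and 101 of them by at least 8-fold. Setting the median of the 19 measured reference genes to 1 moved this to 2469 higher and 408 lower, or 85.8% higher instead of 57.3%. In simulated pairs of libraries, 183 unchanged genes were counted with a coefficient of variation of 0.2 and 2257 with 0.4, and the variation between cultures of these cells was not measured.

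**Figure D2:**
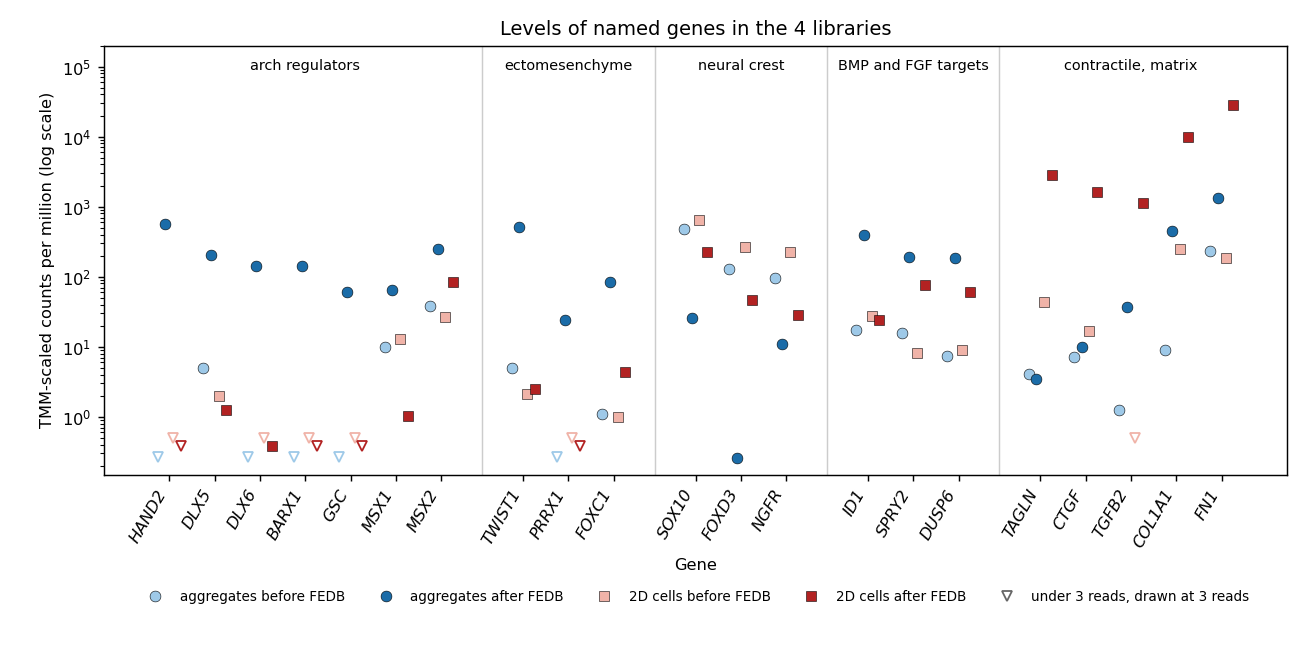
TMM-scaled CPM (y axis, log scale) of named genes (x axis) in the 4 libraries, 1 point per library, with open triangles at the level of 3 reads for genes under 3 reads. HAND2 stands at 566 CPM in aggregates after FEDB and has 0 reads in the other 3 libraries, whereas TAGLN stands at 2814 CPM in 2D cells after FEDB and at 43.2 CPM or less elsewhere.

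The second comparison was 2D cells after against before FEDB. Here the arch regulators did not move as a group. HAND2 had 0 reads before and after, so no level above 0.378 CPM, the equivalent of 3 reads, was found after FEDB. DLX6 had 1 and 3 reads, DLX5 stood at 1.99 and 1.26 CPM, and PRRX1 had 0 reads in each library. MSX1 was 12.8-fold lower (6.18 to 30.7). MSX2 was 3.17-fold (2.67 to 3.79) and TBX3 3.07-fold (2.30 to 4.16) higher. Of the 12 mandibular and distal regulators 3 were higher and 2 lower (median -0.20, percentile 30.7 among random lists), and of 8 maxillary and proximal regulators 3 were higher and 4 lower (median -0.48), with NR2F2 11.3-fold (10.2 to 12.5) and NR2F1 8.33-fold (7.56 to 9.21) lower. TWIST1 stood at 2.15 CPM before and 2.52 CPM after. Of 12 ectomesenchyme genes 3 were higher, FOXC2 at 83.0-fold (28.2 to 405), CDH11 at 32.2-fold (26.4 to 39.7) and PDGFRB at 6.02-fold (5.23 to 6.96), and 2 were lower.

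Genes of contractile cells, of TGF-beta and YAP signalling and of the extracellular matrix were far higher in the 2D cells after FEDB. Smooth muscle and myofibroblast genes were higher in 8 of 9 and lower in none (median 5.40, above every random list, 6.24 with GC correction). TPM1 was 446-fold (352 to 575), ACTG2 163-fold (74.7 to 445), CNN1 73.1-fold (49.4 to 113) and TAGLN 65.1-fold (57.7 to 73.9) higher. TGF-beta and YAP targets were higher in 10 of 12 and lower in none (median 4.85, above every random list, 5.05 with GC correction), with TGFBI at 1349-fold (620 to 3678), THBS1 at 487-fold (312 to 809) and ANKRD1 at least 316-fold. The ligand genes TGFB2 and INHBA were at least 2296-fold and at least 490-fold higher, from 0 reads, and the cell cycle inhibitor gene CDKN2B was at least 396-fold higher. Matrix genes were higher in 12 of 16 and lower in none (median 3.72). FN1 reached 28068 CPM, 153-fold higher (144 to 163), COL1A1 reached 9789 CPM, 39.7-fold higher (37.7 to 41.8), and COL12A1 was 3424-fold (948 to 28280, from 2 reads), COL3A1 560-fold (272 to 1394) and TNC 213-fold (119 to 427) higher. Of 6 bone genes 4 were higher, SPP1 at 146-fold (40.0 to 1206) and RUNX2 at 40.8-fold (11 to 341), each from 2 reads, and COL1A1 and COL1A2, which the matrix list shares.

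Neural crest, neuronal and WNT target genes were lower. Of 15 crest specifiers, 12 were lower and none higher (median -1.96, below every random list, -1.78 with GC correction), including NGFR at 7.92-fold (6.87 to 9.15), FOXD3 at 5.83-fold (5.20 to 6.55), PAX3 at 3.91-fold (3.67 to 4.17) and SOX10 at 2.86-fold (2.71 to 3.03). The transcripts of NGFR, FOXD3 and SOX10 have 62.8%, 64% and 63.5% GC, and their folds here are without GC correction. In the decile with the highest GC content the median log2 ratio for FEDB in 2D cells was -0.49, and in the decile with the lowest it was 0.93. The folds of low-GC genes that were higher, such as TGFB2 (38.9% GC) and INHBA (39.1% GC), are likewise without GC correction. SOX9 was 2.86-fold lower (2.29 to 3.59). TFAP2A stood at 113 CPM before and 87.6 CPM after. Of 10 peripheral neuron genes, 8 were lower and 1 higher (median -4.20, below every random list). NEUROG1, NEUROD1 and ELAVL3 had 0 reads after FEDB and were at least 301-fold, at least 125-fold and at least 58.6-fold lower, and POU4F1 was 505-fold lower (90.2 to 20013), at 1 read. Glial genes did not move together, with 1 higher and 3 lower of 9. GFRA3 was 22.2-fold lower (13.8 to 37.9). WNT targets were lower in 6 of 7 and higher in 1 (median -2.62), with SP5 at least 73.9-fold, NKD1 20.3-fold (16.2 to 25.8) and APCDD1 15.6-fold (9.02 to 29.1) lower. Pluripotency genes were lower in 4 of 6 and higher in 1, with LIN28A 11.4-fold (10.6 to 12.2) and L1TD1 8.06-fold (6.88 to 9.49) lower.

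Feedback targets of FGF and ERK signalling were higher in 7 of 11 and lower in 2 (median 1.61, percentile 99.3), including ETV5 at 20.3-fold (12.7 to 34.5), SPRY2 at 9.10-fold (6.81 to 12.4) and DUSP6 at 6.58-fold (4.97 to 8.86). BMP targets went both ways, 4 higher and 3 lower of 10 (median 0.10, percentile 41.9, and -0.22 to 0.81 over the alternatives). SMAD7 was 9.48-fold (7.25 to 12.6) and the BMP antagonist gene GREM1 44-fold (18.7 to 137) higher, whereas ID1 stood at 27.5 CPM before and 24.1 CPM after. In the endothelin pathway 3 of 7 genes were higher and 1 lower. EDN1, which encodes endothelin-1 itself, was 99.9-fold higher (50.5 to 232) and its receptor gene EDNRA 9.73-fold lower (8.6 to 11). Epithelial genes were higher in 5 of 6 and lower in 1 (median 3.35, and 0.00 to 4.14 over the alternatives), with DSP at 536-fold (95.9 to 21213, from 1 read), KRT18 at 30.7-fold (21.8 to 44.4) and KRT8 at 12.4-fold (10.4 to 14.9). Only these 6 of the 13 listed epithelial genes in the table reached 10 CPM in any library. The cadherin gene CDH1 was among those that did not.

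In total 3108 genes were counted as higher and 1846 as lower out of 9854, 641 and 334 of them by at least 8-fold, and the median log2 ratio over all 9854 was 0.29. The higher share, 62.7%, was 48.9% when scaled to total counts (2391 higher, 2494 lower), 47.5% with upper-quartile scaling (2360 and 2606) and 51.5% with reference genes (2465 and 2318). Of the 19 reference genes, 12 were past 2-fold, with EMC7 3.42-fold (2.78 to 4.24) and VCP 2.83-fold (2.72 to 2.93) higher, against 3 in the aggregates. With the aggregates before FEDB as the baseline in place of that 2D library, 1824 genes were higher and 1314 lower.

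The responses of the culture formats to FEDB were then set against each other gene by gene. Across 10392 genes the log2 ratios correlated at Pearson's r = 0.12 and Spearman's rho = 0.011. Of 8898 genes past the expression minimum in both, 413 were higher in both, where independent lists would share 324, and 215 were lower in both (143 for independent lists). Another 250 were higher in aggregates and lower in 2D cells (176) and 255 the reverse (262). The FEDB ratio differed at least 2-fold between formats for 5867 of 10392 genes, 3469 with the higher ratio in 2D cells and 2398 with the lower. The same held for many of the 19 reference genes, 8 with the higher ratio in 2D cells and 4 with the lower. The count is therefore not a measure of format-specific responses alone.

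The arch and ectomesenchyme regulators had lower FEDB ratios in 2D cells. The ratio of TWIST1 was 87.3-fold (42.0 to 183), that of MSX1 84.4-fold (38.2 to 166), that of DLX5 64.7-fold (26.8 to 151), that of SOX9 8.25-fold (6.39 to 10.6) and that of MSX2 2.03-fold (1.67 to 2.49) lower than in aggregates. Of the mandibular and distal list, 10 of 12 had a lower and 1 a higher ratio in 2D cells, and of the ectomesenchyme list 9 had a lower and 2 a higher ratio. Smooth muscle genes had a higher ratio in 2D cells in 7 of 9 and a lower one in 1, TGF-beta and YAP targets in 9 of 12 and 1, and glial genes in 7 of 9 and 1. The ratio of SOX10 was 6.55-fold higher in 2D cells (5.75 to 7.43), with levels after FEDB of 225 CPM there and 26.0 CPM in aggregates, and those of NGFR (1.12-fold, 0.889 to 1.41) and TFAP2A (1.13-fold, 1.01 to 1.27) differed by less than 2-fold. Among the largest single differences, the ratio was 742-fold higher in 2D cells for the annexin gene ANXA1 (338 to 1490), 266-fold for CLSTN2 (156 to 430) and 137-fold for CDH6 (121 to 154). It was 1002-fold lower for the somatostatin gene SST (507 to 1794).

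**Figure D3:**
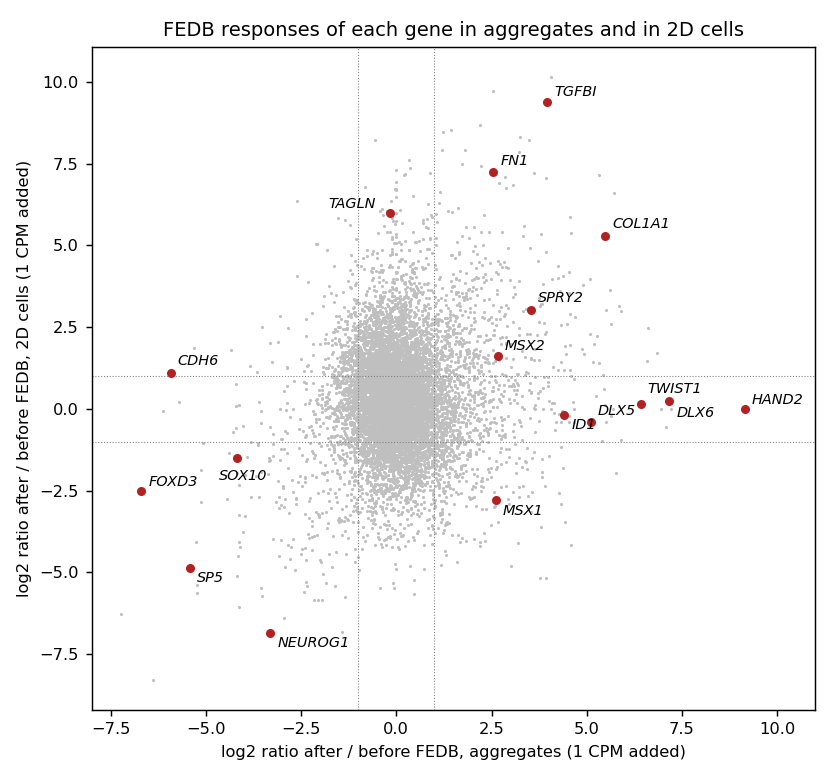
Log2 ratio after over before FEDB of each of 10392 genes in aggregates (x axis) and in 2D cells (y axis), 1 CPM added, with named genes in red and dotted lines at 2-fold. HAND2, DLX5, DLX6 and TWIST1 lie far to the right near 0 on the y axis, and TAGLN lies high near 0 on the x axis, in a cloud whose Pearson's r is 0.12.

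The third comparison set the starting populations against each other, 2D cells against aggregates before FEDB. Of 15 neural crest specifiers, 5 were higher, 2 lower and 8 neither (median 0.40, percentile 94.4, but -0.23 with GC correction), with FOXD3 2.08-fold (1.94 to 2.24, but 1.0 with GC correction) and SNAI1 3.69-fold (3.03 to 4.52, and 2.21 with GC correction) higher and TFAP2A 3.32-fold lower (3.06 to 3.60). Peripheral neuron genes were higher in 8 of 10 and lower in none (median 1.85, percentile 99.9, 1.86 with GC correction), with the sensory regulators NEUROG1 at 8.68-fold (7.25 to 10.4), POU4F1 at 7.61-fold (6.06 to 9.66) and NEUROD1 at 7.08-fold (5.47 to 9.28), and SST was 28.0-fold higher (20.1 to 40.2). Of the 12 mandibular and distal regulators 1 was higher and 2 were lower, with MSX2 at 38.2 CPM in aggregates and 26.6 CPM in 2D cells, and of the maxillary list 2 of 8 were higher and 1 lower, with NR2F2 7.58-fold higher (7.04 to 8.18).

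Among single genes, the lactate transporter gene SLC16A3 was 216-fold (92.2 to 669), ALDOC 26.3-fold (19.3 to 36.5), VEGFA 24.5-fold (17.9 to 34.6), and PDK1 14.1-fold (9.45 to 21.7) higher in the 2D cells, and of 11 hypoxia response genes 4 were higher and none lower (median 1.11). Smooth muscle genes were higher in 4 and lower in 1 of 9 (median 1.0, percentile 99.4, 0.63 with GC correction), TGF-beta and YAP targets higher in 4 of 12 and lower in none (0.95, 99.5 and 0.66), and immediate early genes higher in 4 of 9 and lower in none (1.27, 99.8 and 1.15). COL1A1 was 27.1-fold (22.2 to 33.5) and TAGLN 10.7-fold (7.75 to 15.0) higher. The transcripts of COL1A1, SLC16A3 and NEUROG1 have 61.1%, 62.7% and 60.2% GC, and their folds here are without GC correction. In the decile with the highest GC content the median log2 ratio of this comparison was 0.83. Pluripotency genes were lower in 3 of 6 and higher in 1, with ZFP42 20.4-fold (12.8 to 34.7) and LIN28B 3.93-fold (3.57 to 4.33) lower. Of 18 genes of S phase and mitosis, 12 were lower and none higher (median -1.38, -1.11 with GC correction), among them CCNE2 at 16.4-fold (9.30 to 32.1), BUB1 at 7.43-fold (6.47 to 8.58) and MKI67 at 5.07-fold (4.49 to 5.74). The lowest ratios belonged to RMND5A, 1071-fold lower (192 to 42305), RRP7A, 517-fold lower (92.5 to 20422), HAPLN1, at least 110-fold lower, and NFYC, at least 94.1-fold lower. Each had at most 1 read in the 2D library before FEDB and at least 39.2 CPM in each of the other 3.

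Here 1646 genes were counted as higher and 2400 as lower out of 9529. With upper-quartile scaling the higher share was 55.1% (2283 higher, 1862 lower) instead of 40.7%, and with GC correction 1156 genes were higher and 2263 lower. Of 19 reference genes, 9 were past 2-fold, including PPIA at 5.64-fold (5.31 to 5.99) and RPLP0 at 3.56-fold (3.51 to 3.62) higher.

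The fourth comparison, 2D cells against aggregates after FEDB, leaves out the 2D library before FEDB. The arch and ectomesenchyme regulators were lower in the 2D cells. HAND2 was at least 1496-fold, GSC at least 159-fold and PRRX1 at least 64.2-fold lower, with 0 reads in 2D cells, and BARX1 was 1126-fold (202 to 44510, 1 read in 2D cells), DLX6 375-fold (128 to 1821), TWIST1 201-fold (130 to 329), DLX5 161-fold (87.5 to 336) and MSX1 64.7-fold (32.7 to 150) lower. Of 12 mandibular and distal regulators, 10 were lower and 1 higher (median -4.78), of 8 maxillary and proximal ones 7 were lower and 1 higher (median -2.54), and of 12 ectomesenchyme genes 9 were lower and 1 higher (median -3.76), each median below every random list. BMP targets were lower in 5 and higher in 2 of 10 (median -1.0), with ID2 28.5-fold (22.5 to 36.8) and ID1 16.3-fold (14.1 to 19.0) lower, and FGF and ERK feedback targets lower in 6 and higher in 1 of 11 (median -1.20), with IL17RD 5.19-fold (4.23 to 6.43), DUSP6 3.15-fold (2.85 to 3.48) and SPRY2 2.56-fold (2.34 to 2.81) lower. SOX9 was 5.89-fold (4.86 to 7.19) and TFAP2A 3.75-fold (3.46 to 4.07) lower. Cartilage genes were lower in 4 and higher in 2 of 11. Other genes far lower in 2D cells were PI15 at 1843-fold (330 to 72813) and VCAM1 at 832-fold (149 to 32892), each with 1 read in 2D cells, MAB21L2 at 209-fold (122 to 392), and EBF3, at least 277-fold, with 0 reads.

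Contractile, TGF-beta and YAP target, matrix, glial and epithelial genes were higher in the 2D cells. Smooth muscle genes were higher in 8 and lower in 1 of 9 (median 4.67, above every random list), with TAGLN at 811-fold (597 to 1130), CNN1 at 123-fold (85.5 to 184) and MYL9 at 104-fold (92.5 to 116). TGF-beta and YAP targets were higher in 11 of 12 and lower in none (median 3.90, above every random list), with THBS1 at 369-fold (279 to 499), CTGF at 161-fold (134 to 195) and ANKRD1 at least 617-fold. The collagen crosslinking gene LOX was 1022-fold (349 to 4960), POSTN 114-fold (76.1 to 178), COL1A1 21.9-fold (21.3 to 22.5) and FN1 20.9-fold (20.5 to 21.2) higher, and of 16 matrix genes 10 were higher and 3 lower. Glial genes were higher in 7 of 9 and lower in none (median 3.07, above every random list), with FABP7 at 12.4-fold (9.76 to 15.9) and ERBB3 at 9.83-fold (8.4 to 11.6), and SOX10 was 8.67-fold higher (7.67 to 9.82). The crest specifiers as a list were split, 3 higher and 4 lower of 15. All 6 measured epithelial genes, of 13 listed ones in the table, were higher, with KRT18 at 49.7-fold (36.4 to 69.5) and KRT8 at 20.8-fold (17.7 to 24.6). EDN1 was 312-fold (133 to 964), ANXA1 480-fold (319 to 757) and CDKN1A 17.5-fold (15.2 to 20.2) higher.

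In this comparison 1655 genes were counted as higher and 1292 as lower out of 9690, 313 and 223 of them by at least 8-fold. The higher share of 56.2% was 34.3% with total counts (1073 higher, 2059 lower) and 16.9% with reference genes (720 and 3528), whose own median log2 ratio was 0.65. Under these scalings the median over all genes was -0.26 and -0.63 in place of 0.05.

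Markers of other cell types were mostly below the minimum. Of the lists, none of 15 HOX genes from the anterior part of the clusters, 7 mesoderm genes or 8 endoderm genes reached 10 CPM in any library. Of central neural ectoderm genes 2 of 12 were measured, SOX2 and NES, and NES was 4.61-fold higher in 2D cells than in aggregates after FEDB (4.39 to 4.85). Of skeletal muscle genes only ACTC1 was measured, 74.8-fold higher in 2D cells than in aggregates after FEDB (64.7 to 86.9), and of blood cell genes only CD34, which was 6.93-fold higher after than before FEDB in aggregates (4.88 to 10.1). Of 3 measured endothelial genes 2 were higher and 1 lower after FEDB in aggregates, with KDR 5.33-fold (3.33 to 8.93) and TIE1 2.44-fold (1.84 to 3.25) higher. Of 5 placode genes, 4 were higher and 1 lower after FEDB in aggregates, and 3 were lower and none higher in 2D cells. EYA1 sits in this list and in the maxillary list, and DLX3 in this list and in the mandibular list.

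**Figure D4:**
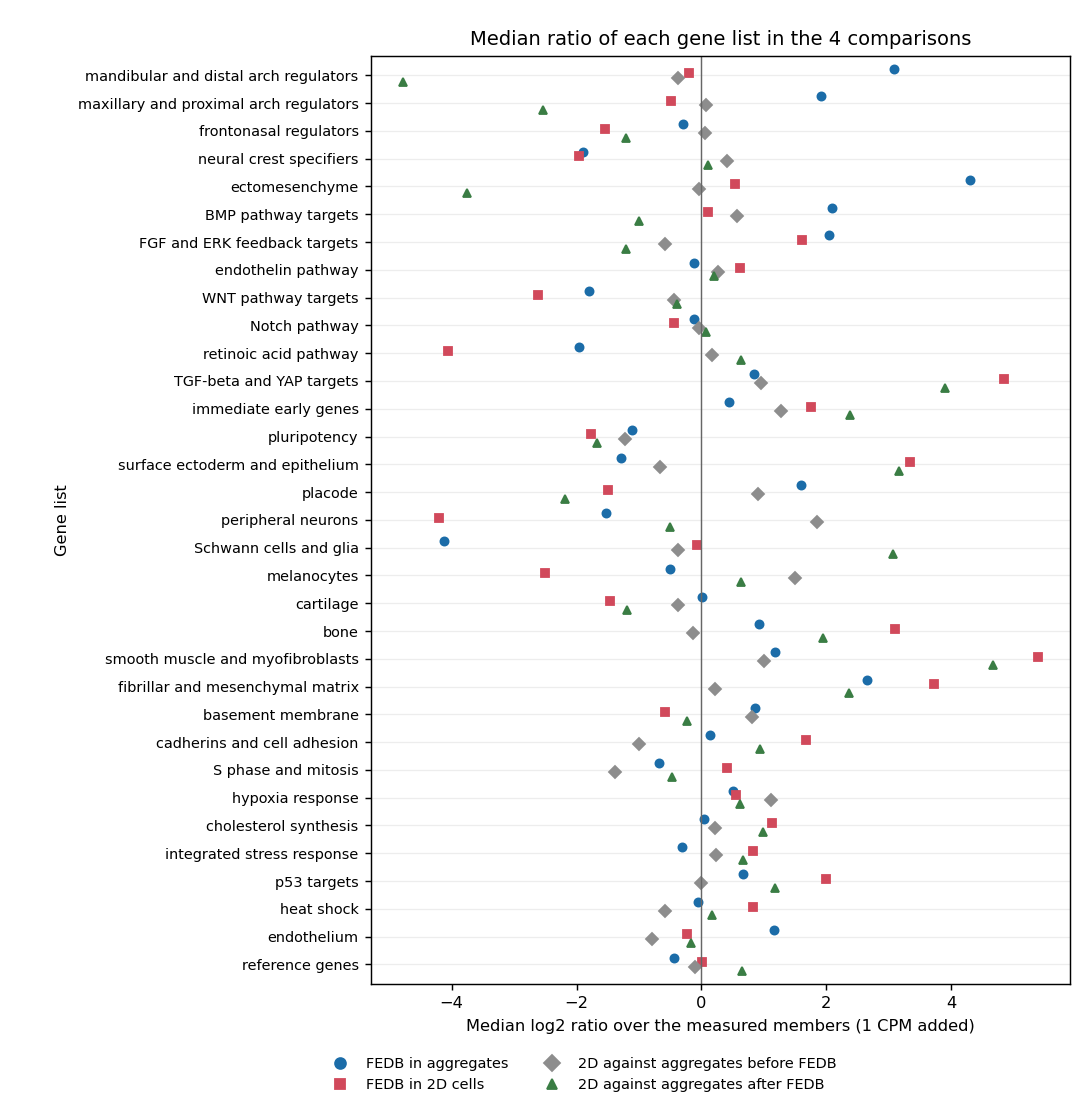
Median log2 ratio (x axis, 1 CPM added) of each list with at least 3 measured genes (y axis), 1 marker per comparison. The mandibular and distal arch regulators lie at 3.09 for FEDB in aggregates and at -0.20 for FEDB in 2D cells, and the smooth muscle genes at 1.18 and 5.40, while the reference gene median for 2D cells over aggregates after FEDB, 0.65, turned to -0.06 when those genes set the scale.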

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

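Of the tests in this part, the correction for GC content as applied to the arch regulators after FEDB was fixed before its result was seen, and the same correction for FEDB in aggregates, the expected reads of HAND2 and the percentile of the ERK feedback targets were chosen after. None of the differences between the culture formats given here was tested, since each group had 1 library.

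MSX1 and SOX9 were higher after FEDB in aggregates and lower in 2D cells: the FEDB ratio in 2D cells was 0.0118 times that in aggregates for MSX1 and 0.121 times for SOX9. Among the lists, the median log2 ratio of the epithelial genes was 4.64 higher in 2D cells and that of the placode genes differed by -3.09, each with opposite directions in the formats. Over the alternatives the epithelial median in 2D cells fell to 0.00 with no minimum, and 2 of 6 epithelial genes were lower in aggregates, while the placode medians went down to 0.385 in aggregates and up to -0.593 in 2D cells. That of the basement membrane genes differed by -1.45, but their median in 2D cells, -0.58, was -0.04 with GC correction, and 5 were higher and 4 lower there. In all, 505 genes were counted in opposite directions. Outside the main measurement, the entries whose gene names had turned into dates held 111696 reads over the 4 libraries, between 0.206% and 0.386% of each.

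The mandibular and distal arch regulators, high after FEDB in aggregates and not in 2D cells, were weighed further. A trend with transcript GC as the whole source of the rise in aggregates is argued against by the small size of that trend. Over deciles of GC the median log2 ratio for FEDB in aggregates lay between -0.23 and 0.27, against 3.09 for this list. A trend of that size left no room for a large fall, and the list median was 2.65 with GC correction. For FEDB in 2D cells the list median of -0.20 was 0.00 with GC correction. For 2D cells over aggregates after FEDB the median was -4.46 with it, which decides nothing, since the ratios there had no trend with GC to remove (rho -0.0089). Shallow sequencing of the 2D cells is argued against by HAND2, for which 4489 reads would be expected in that library at the level of the aggregates and 0 were found. The FGF and ERK feedback targets did rise in the 2D cells, with a median of 1.61 at percentile 99.34 of random lists, and 1.39 with GC correction. Whether this was a response to FGF8b cannot be told, because no cells kept for 4 days without FEDB were analysed. After FEDB these targets were lower in 2D cells than in aggregates in 6 of 11 and higher in 1 (median -1.20), so a weaker ERK response stays open. Of 10 BMP targets, 5 were lower and 2 higher in 2D cells than in aggregates after FEDB. The lower ones include MSX1 and MSX2, which are also among the arch regulators weighed here, so this count partly restates the pattern. ID1 stood at 24.1 CPM in 2D cells and 393 CPM in aggregates, but SMAD7 at 91 and 35.8 CPM. A difference in the competence of the starting cells, in the ERK or BMP response or in the culture format itself may underlie the pattern. These data cannot separate those possibilities.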

How the results depend on the processing

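The GC correction and the exchanged baseline were chosen after the data were seen, all other alternatives before. No paired analysis was possible because each group held 1 library. No named gene counted as higher or lower turned its direction under another scaling, thinning or the GC correction, though ratios could fall under the limit, as those of NGFR (to 1.17) and FOXD3 (to 1.0) for 2D cells against aggregates before FEDB did with GC correction. Genes given only as levels were not included. With DESeq2 size factors, upper-quartile scaling, thinning, a stricter counting interval or the 20 highest amplicons left out of the sizes, every count of genes stayed within 1.5 times its value. Total counts gave 1073 higher and 2059 lower for 2D cells against aggregates after FEDB. Reference gene scaling gave 720 and 3528 there, and 2469 higher and 408 lower for FEDB in aggregates. The median log2 ratio of all genes moved by over 0.1 with that scaling in aggregates (0.39 from -0.05), with total counts (-0.02), upper quartile (-0.05) and reference genes (0.03) for FEDB in 2D cells (from 0.29), and with upper quartile for 2D cells against aggregates before FEDB (0.09 from -0.16). For the same comparison after FEDB it went from 0.05 to -0.63 with reference genes, the largest shift, and to -0.26 with total counts. The causes were not tested.

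Limits act by construction, since a lower one admits more genes. For FEDB in aggregates, higher and lower genes numbered 2365 and 1546 with a minimum of 1 CPM, 2527 and 1667 with none, 515 and 197 at a ratio of 4 and 2126 and 2134 at 1.5, and 732 were higher at 30 CPM. For FEDB in 2D cells, lower genes numbered 3039 with 1 CPM, 3141 with none and 1064 with 30 CPM, and at a ratio of 4 there were 1404 higher and 756 lower. With aggregates before FEDB as the baseline 1824 were higher, 1299 of them also higher against the 2D baseline, and 1314 were lower, 597 of them also lower against it. For 2D cells against aggregates before FEDB, higher genes numbered 2842 with 1 CPM, 3012 with none, 915 with 30 CPM and 2588 at a ratio of 1.5, and at 4 there were 492 higher and 861 lower. For the same comparison after FEDB, lower genes numbered 2445, 2538 and 715 with 1 CPM, none and 30 CPM, and higher and lower ones 596 and 450 at a ratio of 4 and 2726 and 2295 at 1.5. Responses differed at least 4-fold for 2820 genes. The correlation of the responses, 0.12, was 0.119 with reference genes, 0.106, 0.157 and 0.108 with 1 CPM, 30 CPM and no minimum, 0.179 with GC correction, and 0.149 and 0.097 with 0.25 and 5 CPM added, and so stayed low. Of the list medians that lay in the tails of the random lists, that of the cartilage genes for FEDB in 2D cells (-1.46) turned to 0.65 with 30 CPM and 0.0896 with no minimum, which change the members measured, and that of the reference genes for 2D cells against aggregates after FEDB turned to -0.0565 with reference gene scaling, which sets them near 0. Medians outside those tails turned in more cases, such as that of the crest specifiers for 2D cells against aggregates before FEDB (0.40 to -0.23 with GC correction) and that of the frontonasal regulators for FEDB in aggregates (-0.29, and up to 1.75 over the alternatives). Depth limits statements on genes under 10 CPM, where 3 reads are up to 0.496 CPM.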

Other observations

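The tests of GC content on the low genes, of scaling and of the comparison after FEDB in this part were chosen after the results were seen, and the thinning test before.

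The remaining gene lists were counted in the same way. For scale, 1283 of 9436 genes were higher after FEDB in aggregates and 3108 of 9854 in 2D cells. Genes of the retinoic acid pathway were lower after FEDB in both, 2 of 3 measured in each, with CRABP2 38.9-fold (36.3 to 41.8) and CRABP1 3.93-fold (3.69 to 4.19) lower in aggregates and 16.8-fold (15.7 to 18.0) and 65.6-fold (50.2 to 87.3) lower in 2D cells. Immediate early genes were higher in 1 and lower in 3 of 9 after FEDB in aggregates, with FOS 19.4-fold lower (9.16 to 49.3), and higher in 5 and lower in 2 in 2D cells, with IER3 55.8-fold (31.8 to 108) and MYC 10.2-fold (7.49 to 14.3) higher. After FEDB 8 of the 9 were higher in 2D cells than in aggregates, JUNB at 22.1-fold (17.1 to 28.9). Targets of p53 were higher in 2 and lower in 1 of 9 in aggregates and higher in 7 and lower in none in 2D cells, with MDM2 at 19.1-fold (15.8 to 23.2), CDKN1A at 11.5-fold (9.84 to 13.6) and TP53I3 at 10.3-fold (7.5 to 14.6). Cholesterol synthesis genes were higher in 1 of 12 in aggregates and in 6 of 12 in 2D cells, with HMGCS1 at 3.46-fold (3.23 to 3.72). Basement membrane genes were higher in 6 of 12 and lower in none in aggregates, with NID2 at 10.6-fold (8.32 to 13.6), and 5 higher and 4 lower in 2D cells, with COL4A1 at 31.1-fold (27.6 to 35.2). Their median for 2D cells over aggregates before FEDB, 0.81, was 0.08 with GC correction. Cadherin and adhesion genes were higher in 4 and lower in 3 of 10 in aggregates and higher in 7 and lower in 1 in 2D cells, with ITGAV at 37.9-fold (33.2 to 43.4) and CDH2 at 7.75-fold (7.05 to 8.53). The transcripts of ITGAV and MDM2 have 38.3% and 41.9% GC, and their folds here are without GC correction.

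Genes of S phase and mitosis were lower in 6 of 18 and higher in none after FEDB in aggregates, with CCNE2 5.08-fold (3.95 to 6.59) and RRM2 3.56-fold (3.33 to 3.80) lower, whereas 1 was higher and 3 lower in 2D cells (median 0.41, 0.03 with GC correction, against -0.67 in aggregates), and 4 of 18 were lower in 2D cells than in aggregates after FEDB. Of 11 hypoxia response genes 3 were higher in aggregates after FEDB, whereas 5 were higher and 5 lower in 2D cells, with ADM at 63.0-fold (30.4 to 157). Notch pathway genes were 2 higher and 3 lower of 9 in each format, with HEYL 5.49-fold lower in aggregates (4.57 to 6.65) and DLL3 27.6-fold lower in 2D cells (18.7 to 42.2). Of 3 melanocyte genes 1 was lower in aggregates, KIT at 5.09-fold (4.18 to 6.23), and in 2D cells 2 were lower and 1 higher, with PMEL 18.5-fold (13.6 to 25.8) and MITF 7.73-fold (4.66 to 13.5) lower. Integrated stress response genes were 2 higher and 2 lower of 9 in aggregates, with SLC7A11 14.7-fold lower (11.3 to 19.4), and 3 higher and 2 lower in 2D cells, with ASNS at 4.82-fold (3.86 to 6.06). Heat shock genes were 3 higher and 2 lower of 10 in aggregates and 4 higher and none lower in 2D cells, and before FEDB 3 were higher and 3 lower in 2D cells than in aggregates, with HSPH1 11.9-fold lower (9.87 to 14.4). For FEDB in 2D cells the medians of the stress response and heat shock lists lay at percentiles 79.6 and 84.2 of random lists. Ribosomal protein genes took 11.2%, 11.4%, 15.9% and 8.62% of the scaled reads of aggregates before and after and 2D cells before and after FEDB.

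The first pattern weighed was the set of 131 genes low in the 2D library before FEDB alone, whose median transcript GC was 39.8% against 46.1% for all 2164 genes compared. Thinning to the smallest total left the counts of this library as they were, so the 130 such genes found in it then decide nothing alone. Lower depth is argued against by the other libraries, which at that same total had only 2 to 13 such genes each. The trend with transcript GC cannot be the whole source, since 98 were counted after it was removed. The GC of the amplicons themselves or failed amplicons in that library could still contribute and were not tested, and no biological explanation was tested.

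The second was the high level of contractile, TGF-beta and YAP target genes in 2D cells after FEDB. The median of the TGF-beta and YAP targets was at least 4.54 with each of the other 4 scalings. A change of scaling moves all genes nearly alike, and under these scalings and the main one the median of all genes lay between -0.05 and 0.29. It was 0.286 with the 20 highest amplicons left out of the library sizes. The choice among these scalings is thus too small to account for the level of these targets. The GC trend of the 2D library before FEDB is argued against by a median of 3.90 against aggregates after FEDB, a comparison without that library. Plating on fibronectin and 4 days of flat culture without the factors may account for the pattern, and these cannot be told apart from FEDB, because 0 libraries of such cells were analysed here.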
